A study of Mus musculus with 1047 samples.

How the data were processed

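Single microglia of mice were measured by Smart-seq2, 1 cell per GEO sample, and brain cells by 10x droplets. Of 1047 GEO samples, 847 were Smart-seq2 cells of aged animals, 116 were Smart-seq2 cells of the 5xFAD experiment and 75 were cells of postnatal day 14. The labels gave no actinomycin D treatment for the cells of postnatal day 14. The others were 10x libraries of pooled males, 3 titled WT grey matter and 2 titled WT white matter at 24 months, and 4 labelled ApoeKO white matter at 18 months. The white matter library of batch 3 carries the genotype ApoeKO against its WT title, and the title was followed. Per the labels, aged tissue was dissociated with actinomycin D at 45 uM, which blocks transcription, and live cells positive for CD45 and CD11b were sorted. No sort was named for 10x, and myelin was removed with beads. Per the labels, aged Smart-seq2 animals were 18 to 20 months old except A13 at 28 months, and WT animals were male except A1.

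The deposited Smart-seq2 tables hold raw read counts per gene and cell, and the deposited 10x tables hold raw UMI counts per gene and barcode. Per the submitters' processing notes, bcl2fastq, FastQC, Trim Galore and Cell Ranger 4 were used, with mm10. The aligner and the counter of the Smart-seq2 reads were not given in the sources used here. The median depth per cell was 77899 reads in WT grey matter, 89530 in WT white matter, 256184 in Trem2ko grey matter and 284697 in Trem2ko white matter. It was 383162 reads in 5xFAD and 317275 in WT prefrontal cortex. Summed libraries held from 570376 reads (WT grey matter) to 59663083 reads (Trem2ko white matter).

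The aged data held 18081 gene symbols and the 5xFAD data 16012. The aged table joins parts of 358 and 489 cells whose symbols differ, so 55 pairs of renamed symbols were joined. The part of 358 cells holds A11, A12 and A13, all labelled Trem2ko. All WT animals lie in the other part, with A8, A9 and A10, so the parts follow genotype in part. Left out were 4473 genes with 0 reads in all cells of 1 part, which took 0.141% of reads, and 243 genes with 0 reads everywhere, and 13310 genes were kept. Columns that no label tied to a sample, 11224 in all, were not used. In A5, 2 wells were listed more than once (correlation 0.973 to 0.982, against at most 0.498 between other cells of the same animal and tissue).

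Reads were summed per animal and tissue where at least 5 cells were present, which left out A13 and A187. White and grey matter were compared within each genotype, with the difference of their tissue effects, in 1 fit of 22 libraries with the animal as a block. Genotypes were compared in white matter, in grey matter and in prefrontal cortex. edgeR 4.0.16 quasi-likelihood tests with robust dispersion, TMM scaling and filterByExpr were used, at a Benjamini-Hochberg adjusted p of 0.05. The SE of an edgeR log2 fold change was taken as its size over the square root of the F statistic, which is an approximation and unstable near a change of 0. The common biological coefficient of variation was 1.09 in the paired fit, 1.07 in white matter, 1.14 in grey matter and 1.33 in prefrontal cortex. The pairing comes from the animal names in the labels. As a check, deviations from group means correlated between the tissues of 1 animal by 0.0091 to 0.120. In 4 of the 11 animals (A3, A5, A9 and A10) a correlation with another animal was higher than that of the own pair, so the check does not bear out the pairing for them.

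Both tools were tested on simulated data built on the designs, with 200 changed genes each. Between WT tissues edgeR made 1 false call and DESeq2 1.42.0 made 101. In white matter, grey matter and the 5xFAD design, edgeR made 3, 0 and 3 false calls and DESeq2 made 41, 26 and 135. At a 4-fold change between WT tissues, edgeR called 10.4% of changed genes and DESeq2 40.3%.

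Before the data were examined, the samples, comparisons, lists, most alternatives and the rule for naming genes were fixed. Named genes were up to 10 called genes with the largest change in each direction and a mean of at least 20 CPM, with the same sign in every animal in paired fits, a panel of 16 genes, and the 4 members with the smallest p of each list discussed, not all of which are printed. Unnamed gene models, spike-ins, Xist, Tsix and Y-linked genes were left out of the first part. In all, 16 gene lists and 17 marker lists were fixed, and those with at least 3 tested members (21 for the tissue comparisons and the difference of tissue effects, 19 between genotypes in white and in grey matter, 20 for 5xFAD) were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Gene positions were on GRCm38.

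Alternatives covered scaling, tool, filters, cells used, weight of cells, pairing, plates, sex and each left-out animal. There were 29 for WT tissues, 30 for Trem2ko tissues, 28 for the difference of tissue effects, 28 for white matter, 30 for grey matter and 21 for 5xFAD. Of these, 7, 7, 7, 6, 7 and 4 were added after seeing the data.

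The aged 10x table was analysed with scanpy 1.11.5 on cells with at least 500 genes and under 10% mitochondrial UMIs, with 2000 variable genes, 30 components, 15 neighbours and Leiden resolution 1. A cluster took the name of a class with at least 3 markers among its 50 leading genes. Otherwise it was named microglia-like where at least 5 microglia markers were each found in 25% of cells and at most 1 marker of another class stood among its 10 leading genes. Leading genes had to be found in 20% of the cluster's cells. These thresholds were not fixed before the data were examined, nor was the rule that leaves a cluster unnamed where another class has more markers among its 10 leading genes. Scrublet called 4 doublets (0.02%), too few for the call to have worked, so doublets stayed in. Python 3.11.15 and R 4.3.3 were used.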

Results

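Single microglia of aged mice were sequenced by Smart-seq2, a plate method that reads full-length mRNA of 1 cell per well without molecular identifiers. Cells positive for CD45 and CD11b were sorted from the frontal cortex, taken as grey matter, and from a white matter dissection that held the corpus callosum, optic tract and medial lemniscus. The aged set held 847 cells. Of these, 136 white and 147 grey matter cells came from WT mice, and 297 white and 267 grey matter cells from mice labelled Trem2ko, a knockout label for the microglial lipid-sensing receptor Trem2. A further set held 75 prefrontal cortex cells of 5xFAD mice, a transgenic line that deposits amyloid, and 41 cells of WT mice. Each GEO sample of these sets is 1 cell, so reads were summed per animal and tissue, and the animal was the replicate. Summed libraries with 5 or more cells held between 570376 and 59663083 reads. WT libraries of the aged set reached 4206842 reads, whereas 2 animals labelled Trem2ko, A11 and A12, came from more deeply read plates and held from 40223116 to 59663083 reads per library. Plates held 1 genotype each in the aged set, so genotype and plate run cannot be told apart. Sex went partly with genotype as well. Of the WT animals only A1, used in grey matter alone, was labelled female, whereas A9, A10 and A11 of the compared Trem2ko-labelled animals were. Xist and Ddx3y went against the sex labels of A8 and A10. Values in CPM below are reads per 1000000 after scaling of library sizes, given as mean ± SD over animals.

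Trem2 was reported first as a check of the genotype labels. In white matter of animals labelled Trem2ko, unscaled Trem2 was 275 CPM in A8, 380 in A9, 708 in A10, 412 in A11 and 2034 in A12. In their grey matter it was 606 CPM in A8, 590 in A9, 376 in A10, 346 in A11 and 1455 in A12. WT animals ranged from 1799 to 3977 CPM in white and from 2131 to 5216 CPM in grey matter. The animal labelled Trem2ko A12 therefore lay inside the WT range in white matter and below it in grey matter. After scaling of library sizes, A12 at 1856.7 CPM in white matter lay next to the lowest WT animal at 1856.8 CPM. The animal labelled Trem2ko A13 held 2774 and 2281 CPM in its 4 white and 2 grey matter cells, too few for the comparisons. Trem2 lies on chromosome 17 between positions 48346401 and 48354147 of GRCm38. Directions drawn from the Trem2ko label below rest on 5 animals of which A12 goes against the label.

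**Figure D1:**
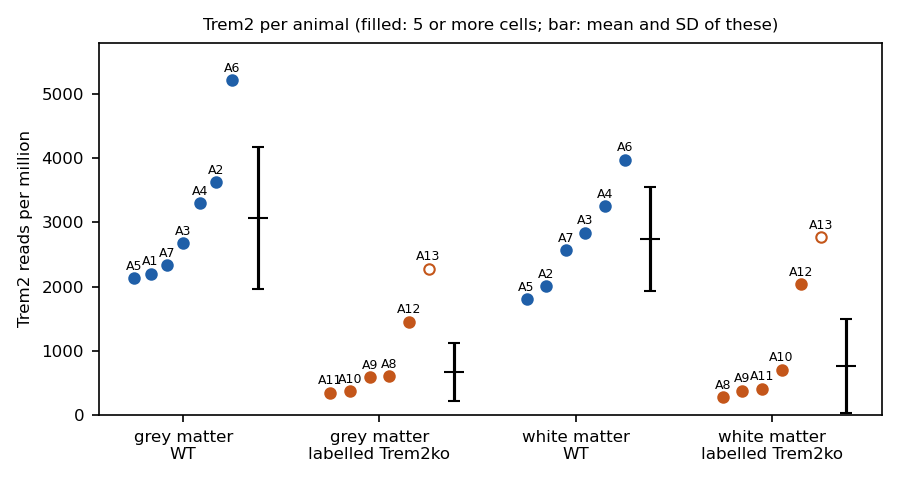
Trem2 reads per 1000000 (vertical axis, unscaled) in each animal, by tissue and genotype label. Filled points are animals with 5 or more cells, open points have fewer, and bars give the mean and SD of the filled points. The animal labelled Trem2ko A12 stands at 1455 CPM in grey and 2034 CPM in white matter, above the other Trem2ko animals with 5 or more cells.

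The first comparison asked how white and grey matter microglia of the same aged WT mice differ. White matter microglia held more Lyz2, H2-D1, Ctsh and Lpl than grey matter microglia in 6 of 6 animals. Lyz2, which encodes lysozyme, averaged 4479 ± 3833 CPM (SD, n = 6) in white and 521 ± 177 CPM in grey matter, 6.46-fold higher. H2-D1, a class I MHC heavy chain, averaged 6110 ± 1531 against 2151 ± 829 CPM, 2.98-fold higher. Ctsh, which encodes the lysosomal protease cathepsin H, averaged 1982 ± 658 against 907 ± 136 CPM, 2.10-fold higher (fitted folds, which need not equal the ratio of the means). Lpl, which encodes lipoprotein lipase, averaged 447 ± 369 against 6.67 ± 12.6 CPM. Its fitted fold of 185 is uncertain, since it rests on grey matter levels under 3 CPM in 5 of 6 animals, and the 2 means lie less far apart. Log2 fold changes were 2.69 ± 0.32 (SE) for Lyz2, 1.58 ± 0.20 for H2-D1, 1.07 ± 0.16 for Ctsh and 7.53 ± 1.17 for Lpl, with adjusted p of 0.0017, 0.0031, 0.013 and 0.016 (edgeR quasi-likelihood, Benjamini-Hochberg). Of 11443 genes tested with the animal as a block, these 4 rose and 0 fell, while 599 had an unadjusted p under 0.05. DESeq2 called 176 genes up and 127 down on the same libraries. In GRCm38 the 4 protein-coding genes lie on chromosome 10 at 117277331 to 117282321 (Lyz2), chromosome 17 at 35262730 to 35267499 (H2-D1), chromosome 9 at 90054152 to 90076089 (Ctsh) and chromosome 8 at 68880491 to 68907448 (Lpl). Lyz2 and H2-D1 have near-identical relatives (Lyz1 and other class I genes), so their counts are uncertain where reads could be shared. Without A2 or A5, 2 genes were called (Lyz2, H2-D1). Without A3 the count was 3 (Lpl lost), and without A4 it was also 3 (Ctsh and Lpl lost, Apoe gained). Without A6 it stayed at 4 with Lpl lost and Capg gained, so the Lpl call ended without each WT animal but A7. With all animals kept whatever their number of cells, 2 genes were called (Apoe and Lpl), and the calls of Lyz2, H2-D1 and Ctsh ended. With only cells of at least 50000 reads, Ctsh and Lpl were lost, and with WT animals fitted alone, Ctsh was lost and Spp1 gained.

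Of the 16 genes of the fixed panel, 1 (Lpl) passed the threshold over all genes between WT tissues, and 13 had an unadjusted p under 0.05. Apoe, the main lipid carrier apolipoprotein of the brain (chromosome 7, 19696109 to 19699188), averaged 46379 ± 39584 CPM in white and 1319 ± 1013 CPM in grey matter (n = 6), 26.1-fold higher in 6 of 6 animals, with adjusted p = 0.064 (edgeR quasi-likelihood, Benjamini-Hochberg). Log2 fold changes of activation genes were 6.91 ± 1.21 (SE) for the secreted phosphoprotein Spp1, 6.66 ± 1.88 for the pattern receptor Clec7a, 5.80 ± 1.45 for Cst7, 7.39 ± 2.63 for Itgax, 4.90 ± 1.66 for Axl and 0.78 ± 0.31 for Cd63. Spp1, Clec7a, Itgax and Axl, like Lpl, were left out of the grey matter comparison of genotypes below for low counts. The size of their fitted changes is therefore uncertain. Those of antigen presentation and interferon genes were 0.74 ± 0.15 for B2m, 2.27 ± 0.90 for Cd74 and 3.61 ± 1.83 for Ifit3. The homeostatic genes P2ry12, Tmem119 and Cx3cr1 had -0.69 ± 0.14, -0.45 ± 0.13 and -0.31 ± 0.19, Trem2 had -0.11 ± 0.23, and the myelin gene Mbp had 3.08 ± 1.24. Without the cells that carry markers of another cell type, Spp1 joined the 4 called genes.

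Gene lists fixed beforehand separated the tissues more clearly in WT animals (camera, 0.01 preset correlation). The homeostatic microglia list fell in white matter (adjusted p = 4.0e-08, and adjusted p = 0.0064 with an estimated correlation), with 17 of 20 members negative and 6 lower when adjusted over the list alone, led by P2ry12, Fcrls, Slc2a5 and Tmem119. Both lists of disease-associated microglia (DAM), published from an amyloid model, rose. Of the stage 1 list, 10 of 10 members were positive and 7 passed adjusted over the list alone, led by Lyz2, H2-D1, Apoe and B2m, with adjusted p = 7.8e-15 by camera and adjusted p = 0.0096 with an estimated correlation. Of the stage 2 list, 13 of 14 were positive and 11 passed adjusted over the list alone, led by Lpl, Spp1, Cst7 and Clec7a, with adjusted p = 1.8e-12 by camera and adjusted p = 0.0064 with an estimated correlation. MHC class I genes rose, 5 of 13 adjusted over the list alone (H2-D1, H2-K1, B2m and H2-Q6 lead; camera adjusted p = 5.4e-07, adjusted p = 0.0064 with an estimated correlation). MHC class II genes rose, 3 of 7 adjusted over the list alone (H2-Ab1, H2-DMa and Cd74, then H2-Oa; camera adjusted p = 7.9e-04, adjusted p = 0.017 with an estimated correlation). Of the integrin, adhesion and matrix list, 10 members rose and 1 fell adjusted over the list alone among 18 tested (Spp1, Capg, Anxa5 and Lgals3 lead; camera adjusted p = 5.4e-07, adjusted p = 0.0071 with an estimated correlation).

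Other lists passed camera in WT animals at the preset correlation and not with an estimated one. The interferon response list had 20 of 21 members positive (Ifi27l2a, Rsad2, Ifi204 and Bst2 lead), with adjusted p = 0.054 with an estimated correlation. The lysosome list had 20 of 25 positive and 7 past the threshold adjusted over the list alone (Ctsh, Ctss, Ctsz and Atp6v1b2 lead), with adjusted p = 0.053 with an estimated correlation. The complement and phagocytic receptor list had 14 of 19 positive (Clec7a, C3, Axl and C1qa lead), with adjusted p = 0.065 with an estimated correlation. The cytokine and chemokine list (Cd14, Cxcl16, Ccl12 and Ccl2 lead) and the glycolysis and hypoxia list (Ldha, Gapdh, Pgam1 and Pkm lead) each had adjusted p = 0.073 with an estimated correlation. Cytosolic ribosomal proteins had 74 of 85 members positive (Rpl32, Rps16, Rpl41 and Rpl36 lead), with adjusted p = 0.17 with an estimated correlation. The lists of cholesterol synthesis (adjusted p = 0.39), lipid uptake, storage and efflux (0.14, against 0.031 by fry), immediate early and dissociation stress (0.69) and cell cycle (0.77) did not pass camera in WT animals.

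**Figure D2:**
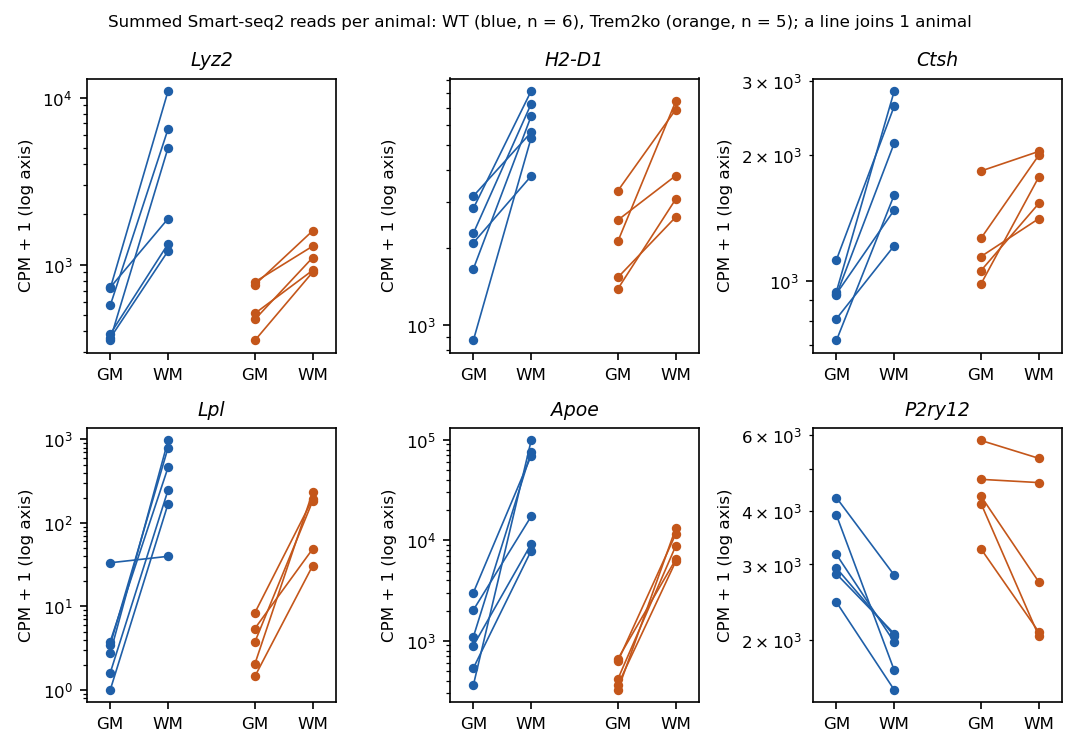
Summed reads per 1000000 plus 1 (vertical, log axis) of 6 genes in grey (GM) and white matter (WM) of each animal, WT in blue (n = 6) and labelled Trem2ko in orange (n = 5); a line joins the tissues of 1 animal. Lyz2, H2-D1, Ctsh, Lpl and Apoe were higher in white matter in 6 of 6 WT animals, and P2ry12 was lower in 6 of 6.

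In animals labelled Trem2ko, white matter microglia had higher mean Apoe and Lpl and lower mean Fcrls than grey matter microglia, and 0 genes passed the threshold in either direction. Apoe averaged 9246 ± 3096 CPM (SD, n = 5) in white and 479 ± 155 CPM in grey matter, 19.2-fold higher in 5 of 5 animals. Lpl averaged 137 ± 91.9 against 3.21 ± 2.80 CPM, 46.3-fold higher in 5 of 5. Fcrls, an Fc receptor-like gene of homeostatic microglia, had a log2 fold change of -1.25 ± 0.23 (SE) and was lower in 5 of 5. The adjusted p was 0.41 for Apoe and 0.26 for Lpl and Fcrls (edgeR quasi-likelihood, Benjamini-Hochberg). Of the 11443 genes, 323 had an unadjusted p under 0.05, and DESeq2 called 39 up and 34 down. Panel log2 fold changes were 5.07 ± 1.56 for Axl, 2.69 ± 1.66 for Clec7a, 0.27 ± 1.44 for Cst7, -0.79 ± 3.15 for Itgax, 1.97 ± 1.19 for Spp1 and 0.19 ± 0.32 for Cd63. They were 0.61 ± 0.16 for B2m, 1.33 ± 0.87 for Cd74, 3.62 ± 1.73 for Ifit3, 0.05 ± 1.29 for Mbp and 0.04 ± 0.26 for Trem2. For P2ry12, Tmem119 and Cx3cr1 they were -0.50 ± 0.15, -0.42 ± 0.14 and -0.33 ± 0.21. With only genes of at least 20 CPM, without the minimum of cells, with the mean of per-cell CPM or with Trem2ko-labelled animals fitted alone, 1 gene (Apoe) passed. With only plates that hold both tissues 1 gene (Tmem119) passed, and without WT A4 or A7, which share the estimate of the spread, 1 gene passed (Apoe or Lpl).

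In the animals labelled Trem2ko, 4 gene lists passed camera with an estimated correlation. The homeostatic list fell, 15 of 20 members negative and 2 past the threshold adjusted over the list alone (Fcrls and P2ry12, then Tmem119 and Selplg), with adjusted p = 0.029 with an estimated correlation. The DAM stage 2 list rose, 13 of 14 positive and 2 adjusted over the list alone (Lpl and Axl, then Csf1 and Igf1), with adjusted p = 0.032 with an estimated correlation. MHC class I genes rose, 3 of 13 adjusted over the list alone (H2-D1, B2m and H2-K1, then Nlrc5), with adjusted p = 0.029 with an estimated correlation. Lipid uptake, storage and efflux genes rose, 2 of 15 adjusted over the list alone (Lpl and Apoe, then Ch25h and Nceh1), with adjusted p = 0.036 with an estimated correlation. The DAM stage 1 list had 7 of 10 members positive and 4 past the threshold adjusted over the list alone (H2-D1, Apoe, B2m and Lyz2), with adjusted p = 0.057 with an estimated correlation. Interferon response (Ifi27l2a, Zbp1, Oas1a, Irf7) and integrin genes (Capg, Anxa5, Anxa2, Vim) each had adjusted p = 0.054 with an estimated correlation. Immediate early genes (Klf2, Ier2, Atf3, Fos) had adjusted p = 0.062 with an estimated correlation, and complement genes (Axl, C4b, Itgb2, Fcgr1) had adjusted p = 0.069 with an estimated correlation. The remaining lists that passed at the preset correlation had adjusted p = 0.12 (lysosome, led by Ctss, Psap, Ctsh and Ctsl), 0.22 (cytokines, led by Tnf, Nlrp3, Tlr2 and Ccl3), 0.11 (MHC class II, led by Cd74, H2-DMb1, H2-DMa and H2-Ab1) and 0.12 (ribosomal proteins, led by Rps19, Rpl41 and Rpl32) with an estimated correlation. For the ribosomal list 73 of 85 members were positive, and its direction turned when only plates that hold both tissues were used. The lists of glycolysis (adjusted p = 0.12), cholesterol synthesis (0.89) and cell cycle (0.83) did not pass at the preset correlation.

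**Figure D3:**
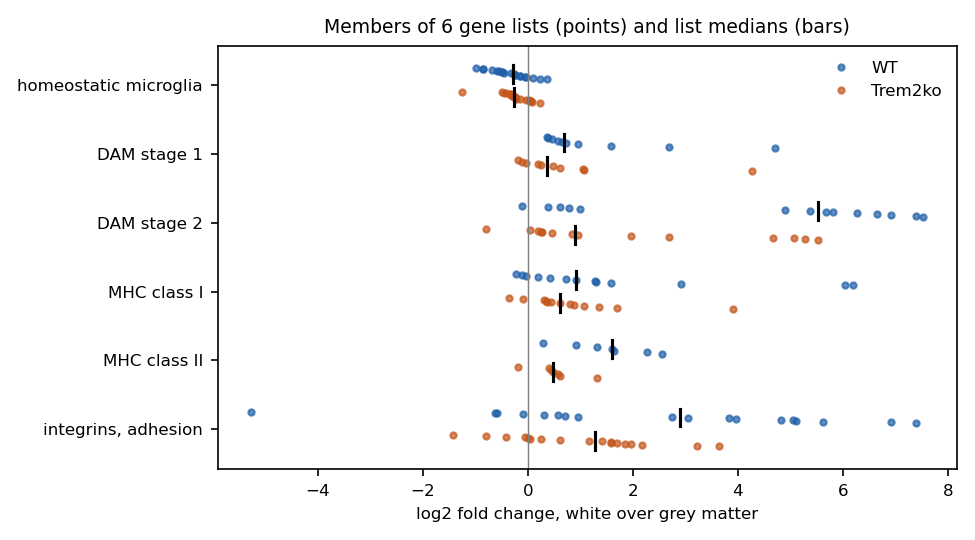
Log2 fold change of white over grey matter (horizontal axis) of each member of 6 gene lists in WT (blue) and Trem2ko-labelled animals (orange), with black bars at the list medians. In WT animals all 10 tested members of the DAM stage 1 list lie above 0, and 17 of the 20 homeostatic members lie below it.

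The next comparison asked whether the tissue difference itself differs between WT and Trem2ko-labelled animals, groups that also differ in labelled sex. The tissue differences of Lyz2 and Spp1 were smaller on average in animals labelled Trem2ko, but 0 genes passed the threshold in either direction. The log2 difference between white and grey matter of Lyz2 averaged 1.05 ± 0.26 (SD, n = 5) in Trem2ko and 2.69 ± 1.18 (n = 6) in WT animals, and that of Spp1 averaged 1.71 ± 3.66 and 5.96 ± 2.47. The fitted difference of tissue effects was -1.65 ± 0.44 (SE) for Lyz2, -4.94 ± 1.63 for Spp1 and -5.53 ± 2.00 for Cst7, each with adjusted p = 1.0 (edgeR quasi-likelihood, Benjamini-Hochberg). In all, 290 genes had an unadjusted p under 0.05, and DESeq2 called 13 up and 18 down. For the rest of the panel the fitted differences were -0.44 ± 0.90 for Apoe, 0.15 ± 0.35 for Trem2, -3.96 ± 2.43 for Clec7a, -2.0 ± 1.35 for Lpl, -8.18 ± 4.42 for Itgax, 0.17 ± 2.12 for Axl and -0.59 ± 0.45 for Cd63. They were 0.19 ± 0.20 for P2ry12, 0.04 ± 0.19 for Tmem119, -0.02 ± 0.28 for Cx3cr1, -0.12 ± 0.21 for B2m, -0.95 ± 1.23 for Cd74, 0.01 for Ifit3 (no SE given, since it was unstable at a change this near 0) and -3.04 ± 1.79 for Mbp. All 10 DAM stage 1 members (led by Lyz2, Ctsd, Tyrobp and Timp2) and 12 of 14 stage 2 members (led by Spp1, Cst7, Itgax and Clec7a) were negative, with adjusted p = 0.0012 and 0.046 by camera. Both had adjusted p = 0.54 with an estimated correlation, and no other list passed. Over 5580 genes of at least 20 CPM, the tissue effects in the genotypes correlated with r = 0.16 (Pearson) and rho = 0.094 (Spearman), across genes, which are not independent replicates. Of these 5580 genes, 3008 (53.9%) had the same sign in both genotypes, and of the 105 among them with an unadjusted p under 0.01 in WT animals, 89 did.

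In white matter, microglia of animals labelled Trem2ko had lower mean Trem2, Apoe and Lyz2 than WT microglia, and 0 genes passed the threshold in either direction. Trem2 averaged 726 ± 655 CPM (SD, n = 5) against 2873 ± 908 CPM (n = 6), Apoe 8838 ± 2895 against 46236 ± 39170 CPM and Lyz2 1107 ± 235 against 4465 ± 3811 CPM. The lowest adjusted p was 0.66, for Trem2 (edgeR quasi-likelihood, Benjamini-Hochberg). Of 8441 genes, 281 had an unadjusted p under 0.05, and DESeq2 called 3 up and 11 down. Log2 fold changes were -1.98 ± 0.43 (SE) for Trem2, -2.39 ± 0.68 for Apoe, -3.12 ± 1.03 for Cst7, -1.76 ± 0.69 for Lpl, -3.04 ± 1.73 for Itgax, -0.96 ± 0.96 for Clec7a, -1.0 ± 0.84 for Axl, -0.49 ± 0.26 for Cd63 and -2.55 ± 1.80 for Spp1. They were 0.64 ± 0.24 for P2ry12, 0.23 ± 0.20 for Tmem119, 0.17 ± 0.17 for Cx3cr1, -0.29 ± 0.19 for B2m, -1.03 ± 0.78 for Cd74, 0.44 ± 1.07 for Ifit3 and -1.95 ± 0.94 for Mbp. Without the animal labelled Trem2ko A12, 1 gene (Trem2) fell.

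Lists of the white matter comparison passed camera at the preset correlation, and 0 of them with an estimated one. DAM stage 1 (10 of 10 negative; Lyz2, Fth1, Apoe and Tyrobp past the threshold adjusted over the list alone) had adjusted p = 0.079 with an estimated correlation. DAM stage 2 (13 of 14 negative; Trem2, Cst7, Lpl and Cd63 lead) had adjusted p = 0.069 with an estimated correlation. The ribosomal list had 80 of 83 members negative and a median log2 fold change of -0.67 (Rpl32, Rps27a, Rps16 and Rps15 lead), with adjusted p = 0.079 with an estimated correlation. The homeostatic list had 17 of 20 positive (Gpr34, P2ry12, Mef2c and Slc2a5 lead), with adjusted p = 0.079 with an estimated correlation. MHC class I (H2-T23, H2-K1, B2m, H2-D1) had adjusted p = 0.11, lysosome (Lgmn, Ctsd, Ctsz, Cd63) 0.12, complement (Trem2, Tyrobp, Fcgr3, Fcgr2b) 0.063, cytokine (Cxcl16, Tnf, Cd14, Tlr2) 0.082, glycolysis (Aldoa, Ldha, Gapdh, Tpi1) 0.063 and integrin genes (Itgb5, Capg, Itgax, Lgals1) 0.082 with an estimated correlation, all lower in Trem2ko-labelled animals at the preset one. By fry, 1 list passed, the homeostatic one (adjusted p = 0.0041). The direction of the lysosome list turned when animals with few cells were kept.

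In grey matter, Trem2 was 4.82-fold lower in animals labelled Trem2ko, at 660 ± 420 CPM (SD, n = 5) against 3181 ± 1287 CPM (n = 7) in WT animals. Trem2 was the 1 gene that fell, with a log2 fold change of -2.27 ± 0.35 (SE) and adjusted p = 0.029 (edgeR quasi-likelihood, Benjamini-Hochberg), and 0 genes rose. The highest Trem2ko-labelled animal, A12, lay below the lowest WT animal (1379 against 2212 CPM). Of 8350 genes, 217 had an unadjusted p under 0.05, and DESeq2 called 6 up and 5 down. Apoe averaged 487 ± 169 against 1590 ± 1078 CPM, with a log2 fold change of -1.71 ± 0.45 and adjusted p = 1.0. The panel log2 fold changes were 2.40 ± 1.35 for Cst7, -0.03 ± 0.29 for Cd63, 0.41 ± 0.17 for P2ry12, 0.19 ± 0.16 for Tmem119 and 0.09 ± 0.18 for Cx3cr1. They were -0.09 ± 0.21 for B2m, 1.23 ± 1.00 for Cd74, 3.11 ± 1.60 for Ifit3 and -0.90 ± 1.25 for Mbp, and 5 panel genes were not tested here for low counts. The ribosomal list had 81 of 82 members negative and 11 lower adjusted over the list alone (Rplp1, Rps29, Rps27 and Rpl37a lead), with adjusted p = 0.095 with an estimated correlation. The complement list (Trem2, Fcgr2b, Cd300a and Gas6 lead) had adjusted p = 0.095 with an estimated correlation, and its direction turned when animals with few cells were kept. Neutrophil markers (Retnlg, S100a8, S100a9 and Csf3r lead) were lower at the preset correlation, with adjusted p = 0.60 with an estimated correlation. The Trem2 call ended without each of A3, A4, A6, A8, A9, A10 and A11, each giving 0 genes. It also ended with all animals kept whatever their number of cells, without cells that carry markers of another cell type, with only cells of at least 50000 reads, without A8 and A10 together, and with animals labelled male only, and 2 genes (Trem2 and Rplp1) fell without A2.

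In the prefrontal cortex, microglia of 5xFAD mice had higher mean Trem2, H2-D1 and Cst7 than those of WT mice, and 0 genes passed the threshold in either direction. Trem2 averaged 3981 ± 1458 CPM (SD, n = 4) against 1822 ± 425 CPM (n = 2), H2-D1 3913 ± 1813 against 1038 ± 687 CPM and Cst7 1232 ± 1232 against 214 ± 266 CPM. Of 9668 genes, 315 had an unadjusted p under 0.05 with edgeR quasi-likelihood, and DESeq2 called 114 up and 37 down. Apoe averaged 40726 ± 32488 against 17635 ± 21665 CPM, and summed unscaled Apoe was 365 CPM in the 5xFAD animal A91 against 32471 CPM in the WT animal A132, where 4 of 14 cells held 10000 CPM or more. Log2 fold changes were 1.13 ± 0.40 (SE) for Trem2, 1.21 ± 2.05 for Apoe, 2.53 ± 1.18 for Cst7, 2.67 ± 1.25 for Axl, 2.14 ± 1.87 for Clec7a, 0.80 ± 1.55 for Lpl, -0.02 ± 2.01 for Itgax, 0.55 ± 0.61 for Cd63 and 3.99 ± 2.66 for Spp1. They were -0.69 ± 0.31 for P2ry12, -0.22 ± 0.29 for Tmem119, -0.81 ± 0.32 for Cx3cr1, 0.55 ± 0.43 for B2m, 1.94 ± 1.79 for Cd74, -0.12 ± 2.10 for Ifit3 and -1.49 ± 1.83 for Mbp. Plates were shared between genotypes for 4 of the animals, A91 with A132 and A99 with A173. With the plate as a block, which left these 4 libraries, 1 gene (Fzr1, named after its values were seen) was called higher in 5xFAD. Log2 fold changes within plates were 0.77 for Trem2, 1.59 for H2-D1 and 2.71 for Cst7, and those of Apoe (-0.74), Lpl (-0.81) and Cd74 (-0.94) turned. Leaving out A91 and A132 was added after the data were seen and left 1 WT animal. A91 was the lowest 5xFAD and A132 the higher WT animal for Apoe. The same held for unscaled Lpl (2.2 CPM in A91, 618 in A132, 10.1 in WT A173). Leaving them out thus raises both genes in 5xFAD by construction, so no call was read from this fit. Without a filter on low counts, 14 genes were called up and 2 down.

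Lists of the 5xFAD comparison passed camera at the preset correlation, and 0 of them with an estimated one. Higher in 5xFAD at the preset one were DAM stage 1 (H2-D1, Lyz2, Ctsb, Timp2; 10 of 10 positive) and stage 2 (Gpnmb, Trem2, Igf1, Cst7; 14 of 16 positive). Interferon (Oasl2, Ifi27l2a, Bst2, Irf7), lysosome (Npc2, Ctsz, Cd68), glycolysis (Tpi1, Aldoa, Ldha, Gpi1) and integrin genes (Capg, Itgav, Lgals3, Anxa5) were higher likewise. Lower were the homeostatic list (Cx3cr1, P2ry12, Csf1r, P2ry13; 17 of 20 negative) and the microglia markers. Each of these 8 lists had adjusted p = 0.41 with an estimated correlation. MHC class I (H2-D1, H2-T23, Psmb9, H2-K1) and cytokine genes (Ccl12, Nfkbiz, Tnf, Cxcl16), also higher at the preset correlation, had adjusted p = 0.41 with an estimated correlation.

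Marker lists of other cell types showed what else the sort could hold. Microglia markers fell in white matter in WT animals (P2ry12, Fcrls, Tmem119 and P2ry13 lower adjusted over the list alone; adjusted p = 0.0096 with an estimated correlation) and in animals labelled Trem2ko (adjusted p = 0.032 with an estimated correlation). Every member of this marker list is also on the homeostatic list above, so its fall is not a separate result. Between WT tissues, camera gave adjusted p = 0.12 for oligodendrocyte markers, whose 6 tested members summed to 526 CPM in white and 405 CPM in grey matter. For these markers fry gave adjusted p = 0.024, with 4 of 6 members positive and a median log2 fold change of 1.58. Camera gave 0.076 for neutrophil markers, 0.076 for B cell markers (median log2 fold change -0.51, mean 0.17; Ighm lower adjusted over the list alone) and 0.62 for border-associated macrophage markers (median -0.69, mean 0.19). For the last 2 lists camera's direction, down, followed the median and not the mean. Fewer than 3 members were tested of the monocyte and dendritic cell, astrocyte, endothelial and neuroblast lists, so those lists had no camera test. In the 5xFAD comparison 1 member each of the T and NK cell, oligodendrocyte progenitor, neuron, pericyte and choroid plexus lists was tested. The neuron member Rbfox3 averaged 10.1 CPM in 5xFAD and 0 in WT animals, with adjusted p = 0.044 over its list of 1 tested gene and 1.0 over all genes. In the same order, 5xFAD against WT, the choroid plexus member Folr1 averaged 16.9 and 0.203 CPM, Cspg4 of the progenitor and pericyte lists 8.61 and 0.623, the 2 endothelial members summed to 23.9 and 4.79, and the T and NK cell member Klrd1 averaged 0.726 and 0.826, none past the threshold over its list. No member of the fibroblast, ependymal and erythrocyte lists was tested anywhere. In the aged set, 95 of 847 cells held 3 or more genes of another cell type, 69 of them of neutrophils and 24 of oligodendrocytes.

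Droplet data (10x, with molecular identifiers, UMIs) of pooled brains held cells of aged WT white and grey matter in 1 table. Its barcodes carry 5 endings, as many as there are WT libraries, but no label ties an ending to a library or tissue, so the table was not compared between tissues. The endings were far from alike. Spp1 was 7.78 and 3.47 UMIs per 10000 in endings 1_2_1 and 1_2_2, which held 29585 and 13377 of its 43743 UMIs, and 0.043 to 0.10 in the other 3. Apoe was 180.6 and 187.2 against 42.9 to 55.6 UMIs per 10000, and Lpl was found in 31.3 and 27.6% of cells against 1.01 to 1.23%. These groups of 2 and 3 endings match in number the 2 libraries titled white and the 3 titled grey matter. This match was not tested and was not used to assign endings. Values of the whole table below pool these endings, and ambient RNA was neither measured nor removed. Of 21197 cells, 20495 had at least 500 genes and under 10% mitochondrial UMIs, with a median of 7131 UMIs per cell before this filter. Microglia-like clusters held 10148 cells, 49.5% of those kept (95% exact binomial interval 48.8 to 50.2%, counting error only). An unnamed cluster of 727 cells with microglia markers is not among them. Astrocyte-like cells made up 13.5%, T and NK cell-like cells 5.69% and endothelial-like cells 5.66%. No sort was named for these cells.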

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

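The tests chosen only after the result was seen were those of a wrong genotype label of A12, of cells of 2 genotypes in its wells by tissue, and of exchanged labels of A91 and A132. In 9 of 100 groups and genes, 1 animal lay far from the others of its group, measured as its gap to the nearest animal over the range of the group, where chance gives about 1 in 20. Low animals were A91 among 5xFAD for Apoe (0.854), Clec7a (0.903) and Lpl (0.939), A9 in Trem2ko white matter for Axl (0.779) and A6 in WT white matter for Cst7 (0.637). High animals were A8 in Trem2ko white matter for B2m (0.776), A3 in WT grey matter for Clec7a (0.667), A12 in Trem2ko white matter for Itgax (0.878) and A7 in WT grey matter for Itgax (0.870). Tissue effects differed between genotypes for the DAM stage 1 list (camera adjusted p = 0.0012, mean log2 difference -0.55, 10 of 10 genes below 0) and the DAM stage 2 list (camera adjusted p = 0.046, mean -2.27, 12 of 14 below 0). With an estimated correlation, camera gave adjusted p = 0.54 for both lists. Over the alternatives, the adjusted p ranged from 5.5e-06 to 0.54 for DAM stage 1 and from 0.0016 to 0.54 for DAM stage 2. In data outside the comparisons, the ApoeKO 10x table held 61.996 Apoe UMIs per 10000 in columns L8 (1645 cells) and 0.177 in columns L7 (1085 cells). Another 11224 columns of this table were not used. Apoe in L8 goes against an ApoeKO label. No label ties columns L7 or L8 to the 4 libraries labelled ApoeKO, so their genotype is not known. In the cells of postnatal day 14, Fos had a read in 14.67% of cells (11 of 75, exact binomial 95% interval 7.56 to 24.7%), and nothing was tested on its induction or on treatment.

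In the animal labelled Trem2ko A12, Trem2 was 1455 CPM in grey and 2034 CPM in white matter, against 2131 to 5216 and 1799 to 3977 CPM in WT animals. The planned test over both tissues found 4.4% of its cells (8 of 182, exact binomial 95% interval 1.92 to 8.48%) at or under the median Trem2 of the A11 cells, under the bound of 10% set before. A median leaves 50.0% of the A11 cells at or under it by construction. In A8, A9 and A10 the share was 27.3 to 34.3% in grey and 20.6 to 50.0% in white matter, so the bar rests on which animal stands for knockout cells. By tissue, tested after these values were seen, the share was 1.2% (0.03 to 6.53%) in grey matter, which argues against knockout cells beyond a minority there. It was 7.07% (2.89 to 14.03%) in white matter, where the first quartile was 137 CPM against 429 to 2254 CPM in WT animals. Knockout cells stay open in white matter, and these values do not limit them to a minority. A wrong genotype label stays open, since A12 lay inside the WT range in white matter and below it in grey matter, -1.464 SD from the WT mean. No biological explanation was tested.

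Apoe was 365 CPM in the animal labelled 5xFAD A91 and 32471 CPM in the animal labelled WT A132, against 2653 CPM in WT A173, and the sum of A132 rests on few cells (4 of 14 at 10000 CPM or more, the highest 275197, median 1957, against medians of 10453 to 51529 CPM in A93, A99 and A100). No draw of 10000 draws of 7 cells from A93, A99 and A100 held Apoe as low as A91. With the real value counted, this is 0.01%, the smallest share the draws can give. It argues against few cells as the cause in A91, were its cells like those of these animals. The 5xFAD animal A187, whose 3 cells had a median of 771 CPM, was not drawn from. Other members of the DAM lists were lower in A91 than in A132 for 21 of 24 genes (median log2 difference -1.015, exact two-sided sign test p = 0.000277 across genes, which are not independent replicates). These values met the first bar for an exchange of labels, but with a condition on A132 added after its values were seen it stays open, since A91 lay below each of the other 3 5xFAD animals for 21 of the 24 and A132 above WT A173 for 21, but A132 below each of A93, A99 and A100 for 13, among them Trem2 (2092 against at least 3826 CPM), Gpnmb (0.473 against 29.2), Igf1 (0.947 against 44.1) and Fabp5 (2.84 against 39.9). A different response of these animals stays open and was not tested.

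Between WT tissues, edgeR called 4 genes and DESeq2 called 303. Of 32 exchanges of tissue labels within WT animals, only the real one (1 of 32) gave as many genes with DESeq2. This met the bar set before, at the smallest share that 32 exchanges can give. The other 31 still gave 78 to 287 genes (median 147), the most with A6 alone exchanged, which keeps the real labels of the other animals. The exchanges therefore do not exclude chance for the genes called. Whether single animals carry the calls stays open, since leaving out A2 kept 50.83% of them (154 of 303, exact binomial 95% interval 45.0 to 56.6%), and leaving out A7 kept 77.9%. The use of that interval was decided after the value was seen. No biological explanation was tested.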

How the results depend on the processing

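The tests chosen only after results were seen were the 8 added alternatives, namely only genes of at least 20 CPM, no ribosomal RNA gene model, only cells of at least 50000 reads, symbols as deposited, repeated wells counted once, and leaving out A11 and A12, A8 and A10, or A91 and A132. Of 308 counts of called genes over all alternatives, 261 stayed near the reported count and 47 moved from it by more than a ratio of 1.5 or to or from 0. Of 5971 values of single genes, 5737 kept their direction and their side of the threshold, 126 reversed, 82 newly passed and 26 no longer passed. Of 1380 values of lists, 1200 stayed, 177 no longer passed and 3 reversed. Between WT tissues, 7 lists kept passing under all 28 alternatives that gave list values, with adjusted p by camera or fry of 2.7e-18 to 0.0096 for DAM stage 1, 7.4e-15 to 0.0064 for DAM stage 2 and 6.9e-08 to 0.0064 for MHC class I. The ranges were 7.3e-05 to 0.017 for MHC class II, 5.5e-11 to 0.0064 for homeostatic genes, 2.6e-08 to 0.0071 for integrins and 2.3e-09 to 0.0096 for microglia markers. These lists overlap, since all microglia markers are also homeostatic genes. B2m and H2-D1 stand on the DAM stage 1 and MHC class I lists, and Spp1 and Itgax on the DAM stage 2 and integrin lists. Between Trem2ko tissues, 4 lists kept passing under all 29 by camera or fry, with adjusted p of 8.5e-08 to 0.035 for DAM stage 2, 3.9e-06 to 0.029 for MHC class I, 1.8e-10 to 0.029 for homeostatic genes and 1.0e-05 to 0.036 for lipid genes. DESeq2 gave no list values, and genes that an alternative no longer tested gave none. Requiring 1000 genes per cell removed 0 cells, and requiring an age of 6 or 7 months removed no animal of the comparison, so neither setting says anything about stability. On simulated data of these designs edgeR called 36.4% of 8-fold changes between WT tissues and 7.58% in the 5xFAD design, and neither depth nor spread was varied, so their part in the low counts was not tested. The planned 10x comparisons and their alternatives were not run, because no label tied cells to libraries.

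The values that follow are numbers of called genes and log2 fold changes of single genes whose sign turned, and for each the cause was not tested. The DESeq2 Wald test gave 176 genes higher, 127 genes lower (WT tissues) and 39 genes higher, 34 genes lower (Trem2ko tissues). It also gave 13 genes more positive, 18 genes more negative (the difference of tissue effects) and 3 genes higher, 11 genes lower (white matter). It also gave 6 genes higher, 5 genes lower, Cx3cr1 -0.0016 (grey matter) and 114 genes higher, 37 genes lower (5xFAD). The mean of per-cell CPM with limma-trend gave 11 genes higher, 2 genes lower (WT tissues) and 1 gene higher, Cd63 -0.057 (Trem2ko tissues). It also gave Axl -0.21, Cx3cr1 0.069, Ifit3 -0.96 (the difference of tissue effects) and 1 gene higher (white matter). It also gave Cd63 0.21, Mbp 0.065 (grey matter) and Cd74 -0.53 (5xFAD). Keeping all animals without a minimum of cells gave 2 genes higher (WT tissues, Apoe and Lpl, so that Lyz2, H2-D1 and Ctsh were no longer called) and 1 gene higher, Trem2 -0.14 (Trem2ko tissues). It also gave Trem2 -0.026, Axl -0.73, P2ry12 -0.28, Tmem119 -0.10, Ifit3 -0.85 (the difference of tissue effects) and Cd63 0.31, Ctsd 0.16, Ctsz 0.49, Aldoa 0.024, Ldha 0.89, Gapdh 0.36, Tpi1 0.14, Capg 0.85, the list lysosome (camera adjusted p = 0.37) (white matter). It also gave 0 genes lower, Cd63 1.05, B2m 0.55, Gas6 2.00, the list complement and phagocytic receptors (camera adjusted p = 0.96) (grey matter). Keeping only genes of at least 20 CPM gave 7 genes higher (WT tissues) and 1 gene higher (Trem2ko tissues). It also gave Ifit3 -0.017 (the difference of tissue effects). Keeping only cells of at least 50000 reads gave 2 genes higher (WT tissues) and Mbp -0.20 (Trem2ko tissues). It also gave Cx3cr1 0.084 (the difference of tissue effects) and 0 genes lower, B2m 0.00699 (grey matter). Leaving out cells that carry markers of another cell type gave Mbp -0.22 (Trem2ko tissues) and Axl -0.15, Cx3cr1 0.049, Ifit3 -0.58 (the difference of tissue effects). It also gave 0 genes lower, Cd63 0.018 (grey matter) and Itgax 0.034 (5xFAD). Leaving out A11 and A12 gave Trem2 -0.25 (Trem2ko tissues) and Trem2 -0.16, P2ry12 -0.13, Ifit3 -0.53 (the difference of tissue effects). It also gave Cx3cr1 -0.12 (white matter) and B2m 0.18 (grey matter). Leaving out A8 and A10 gave Cst7 -1.41, Itgax 1.25, Cx3cr1 0.024, Mbp -0.23, Ccl3 0.072 (Trem2ko tissues) and Axl -0.94, Tmem119 -0.14, Cx3cr1 0.34, Ifit3 -1.26 (the difference of tissue effects). It also gave Tmem119 -0.069 (white matter) and 0 genes lower, Cx3cr1 -0.061 (grey matter). Fitting each genotype alone gave 1 gene higher (Trem2ko tissues). Keeping only plates that hold both tissues gave 1 gene lower, Cst7 -0.58, Itgax 2.33, H2-DMb1 -0.11, Anxa2 -0.036, the list cytosolic ribosomal proteins (camera adjusted p = 0.27) (Trem2ko tissues) and Axl -0.16, Tmem119 -0.38, Cx3cr1 0.20, Ifit3 -1.90 (the difference of tissue effects). Size factors of DESeq2 gave Ifit3 -0.025 (the difference of tissue effects) and Cx3cr1 -0.0016 (grey matter). Testing without a filter on low counts gave Cd63 0.074 (grey matter) and 14 genes higher, 2 genes lower (5xFAD). Sex as labelled, which goes against Xist and Ddx3y in A8 and A10, gave as a covariate Cd63 0.058, B2m 0.015, Cd74 -0.053 (grey matter). Keeping labelled males only, which left A8 and A12 of the Trem2ko animals, gave 0 genes lower, Cd63 0.14, Cd74 -1.02, Ifit3 -0.032, Mbp 0.87 (grey matter). The plate as a fitted factor gave 1 gene higher, Apoe -0.74, Lpl -0.81, Cd74 -0.94 (5xFAD). Leaving out A91 and A132, which left 1 WT animal, gave Itgax 4.53, Ifit3 0.0051 (5xFAD).

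Between WT tissues, 2 genes were higher in white matter without A2 and without A5, and up to 5 without another animal. Between Trem2ko tissues, 1 gene was called without A4 or A7, which are WT animals, and 0 without each of the others. In white matter, 1 gene was lower in Trem2ko without A12. In grey matter, 2 genes were lower without A2 and 0 without A3, A4, A6, A8, A9, A10 or A11. With 1 animal left out, the log2 fold change of Trem2 between WT tissues ran from -0.20 (without A3) to 0.020 (without A2). Between Trem2ko tissues the ranges were Trem2 -0.23 (without A10) to 0.31 (without A8), Cst7 -0.76 (without A8) to 1.13 (without A11), Itgax -2.87 (without A12) to 2.75 (without A10), Mbp -0.78 (without A10) to 0.83 (without A12), H2-Ab1 -0.067 (without A12) to 1.08 (without A8). For the difference of tissue effects they were Apoe -0.80 (without A2) to 0.11 (without A4), Trem2 -0.11 (without A10) to 0.42 (without A8), Axl -0.88 (without A2) to 1.00 (without A3), Tmem119 -0.079 (without A10) to 0.15 (without A12), Cx3cr1 -0.23 (without A12) to 0.14 (without A8), Ifit3 -1.33 (without A7) to 1.30 (without A2). In grey matter they were Cd63 -0.15 (without A5) to 0.17 (without A2), Cx3cr1 -0.0033 (without A2) to 0.20 (without A12), B2m -0.21 (without A9) to 0.044 (without A12), Cd74 -0.19 (without A9) to 1.52 (without A12). For 5xFAD against WT they were Lpl -0.19 (without A173) to 5.97 (without A132), Itgax -1.60 (without A99) to 4.12 (without A132), Cd63 -0.051 (without A173) to 1.56 (without A132), Ifit3 -0.96 (without A99) to 0.28 (without A93). For all of these the cause was not tested.

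The tissues were paired by animal. With no replicate block, the fit gave 9 genes higher, 1 gene lower (WT tissues), and Itgax 0.40, Ccl3 0.16 (Trem2ko tissues). It moved no other count of called genes, and the cause was not tested.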

Other observations

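The tests here were all chosen before their results were seen, but the names of the 10x clusters rest on thresholds set after seeing the data. Microglia-like clusters of the aged 10x table differed in their leading genes. The values below pool 5 barcode endings that no label ties to a tissue, and ambient RNA was neither measured nor removed. A cluster of 3569 cells was led by homeostatic genes, among them P2ry12, Fcrls and Siglech, and held 12.6 Apoe UMIs per 10000 (28.3 and 48.6 in endings 1_2_1 and 1_2_2, 6.36 to 7.68 in the other 3). A cluster of 941 cells led by Spp1, the chemokines Ccl4 and Ccl3, the lipase Lpl, Igf1, Lgals3 and Itgax held 450 Apoe UMIs per 10000, and 469 and 439 of its cells carried endings 1_2_1 and 1_2_2 (463 and 457 Apoe UMIs per 10000, against 9.72 to 67.2 in the other 3). A cluster of 2355 cells led by Rxrg and the receptor Axl held 251, with 1083 and 1181 cells of these 2 endings (246 and 270, against 3.79 to 30.7). A cluster of 270 cells led by Cxcl13 and the interferon-induced genes Ifit2, Ifi204 and Ifit3 held 177, with 74 and 160 cells of them (175 and 209, against 4.45 to 7.0). Outside microglia Apoe followed the ending in some clusters only. A cluster of 1069 T and NK cell-like cells held 78.3 and 53.8 in these 2 endings and 2.35 to 7.07 in the others. By contrast, a cluster of 325 pericyte and smooth muscle-like cells held 13.9 and 13.4 against 16.0 to 25.9. Apoe thus varied with both cluster and ending, and the parts of ambient RNA and of tissue were not tested. These values are therefore not read as expression of the cells that hold them. A cluster of 123 cells was led by C5ar1, Cd83, Gpr84 and Atf3. No test between tissues or genotypes was run on these clusters.

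A cluster of 727 cells led by Ighd and Cd79b, with P2ry12 and Fcrls also among its leading genes, stayed unnamed by the rule on other markers. It held 31.5 P2ry12 and 43.1 Cx3cr1 UMIs per 10000, against 28.8 and 40.7 in the microglia-like cluster of 3569 cells. Cd74 was 0.236, against 86.1 in the B cell-like cluster. Its cells, 3.55% of those kept, are not in the microglia-like share at resolution 1. A cluster of 268 cells led by H2-Eb1, H2-Aa, H2-Ab1 and Cd74 also stayed unnamed. A cluster of 211 monocyte or dendritic cell-like cells was led by Plac8, Mki67, Chil3 and Top2a. Microglia-like cells made up 49.5% of the cells at Leiden resolution 1 and 52.1% at resolution 0.5.

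In the 75 cells of postnatal day 14, which held 9364 to 110716 reads, P2ry12 had a median of 12516 CPM (quartiles 9131 and 15952) and a read in 74 cells. Jun had a read in 31 of these cells, Junb in 37, Egr1 in 13, Btg2 in 51 and Rhob in 70. In A8, labelled male, Xist was 53.1 CPM in grey and 33.2 CPM in white matter, and Ddx3y was 0 and 0.28 CPM. In A10, labelled female, Xist was 0 and 0.55 CPM, and Ddx3y was 8.26 and 0.28 CPM.

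Other splits of the animals were counted for each edgeR comparison. Between WT tissues, 1 of 32 exchanges of tissue labels, the real one, gave as many as 4 genes, and the highest other gave 0. This met the bar set before and argues against chance for the count, at the smallest share that 32 exchanges can give. For lists between WT tissues, 1 of 32, the real one, gave as many as 13, which met the bar set before. The highest other gave 12, with A6 alone, A7 alone, or A3, A4, A5, A6 and A7 exchanged. The last equals A2 alone exchanged with the direction turned. Each of these therefore keeps the real contrast in all WT animals but 1. Exchanges of 3 animals gave 0 to 5 lists, and the median of the other 31 exchanges was 2. The narrow margin over 12 thus says little about chance, which is still not excluded for the lists. Between Trem2ko tissues, edgeR called 0 genes (323 at an unadjusted p under 0.05; DESeq2 called 73), 16 of 16 exchanges reach a count of 0, the highest other gave 0, and 16 exchanges are too few for a share under 0.05 in any case. For the difference of tissue effects, edgeR called 0 genes (290 unadjusted; DESeq2 called 31), every one of 30 splits reaches such a count, the highest gave 1, and the splits say nothing about chance. In white matter, edgeR called 0 genes (281 unadjusted; DESeq2 called 14), 100 of 100 splits reach a count of 0, the highest gave 1, and the splits say nothing about chance here either. In grey matter, 3 of 100 splits, the real one included, gave as many as the real 1 gene, and the highest other gave 1. This share met the bar set before, but a count of 1 gene that other splits also reach does not exclude chance. The count fell to 0 without A3, A4, A6, A8, A9, A10 or A11.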
